A study of Mus musculus with 45 samples.

How the data were processed

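Messenger RNA was purified with poly-T beads from 1 µg of total RNA of each culture, fragmented, copied with random primers and amplified by PCR before sequencing, per the labels' protocols. Whether the libraries keep the strand of the RNA, and whether counting used it, is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and values of near-identical genes such as the tubulins are uncertain where reads could be split among copies. The values came as 9 tables, each comparing 2 groups of 5 libraries, with 30679 to 31290 genes per table and 26202 genes in all 9. The deposited counts are whole numbers of reads per gene, and CASAVA 1.8, STAR 2.5, HTSeq 0.6.1, DESeq2 2 and genome build mm10 are named, without their roles or settings, per the submitters' processing notes. A normalised signal column for each library holds the count divided by 1 size factor, set by the authors separately in each table. FPKM columns scale the counts by the length of each gene and the depth, per the file headers. Each table also holds a log2 fold change, a p-value and an adjusted p-value per gene from the authors' own comparison. Only the deposited counts entered the tests made here, the FPKM and normalised signal columns were used for checks alone, and 0 value columns belonged to no labelled sample.

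A library's counts were equal in every table that holds it (1345730 values compared, 0 unequal). Of 36300 gene identifiers, 36262 were found in the GENCODE mouse release 21 annotation of mm10, and 24 symbols that had been turned into dates were restored by identifier. Coordinates and gene types are those deposited with the counts, from an annotation release that is not given. Groups were taken from the sample titles. For the 50 µM libraries of 3 h, a label field gives a treatment of 24 hours where title and name give 3, and the title was followed. The treatment text of every sample names a culture of 3 hours, although titles give 3, 24 and 48 h, and the titles were followed there too. In the 10 µM group of 48 h, the library codes of replicates 1 and 2 are exchanged against the titles, and both numberings were tried. Counts of PCR reads without molecular identifiers are not independent molecules.

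Each comparison with vehicle, and each comparison between times in vehicle, was fitted on its 10 libraries alone with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test, TMM normalisation, a filter on low counts (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05. A gene below that threshold is said to have been called, or to have risen or fallen. The comparisons of 50 with 10 µM and the differences in the effect of 50 µM between times (interaction terms) were taken from a fit of all 45 libraries. Fold changes of single genes carry a standard error derived from the test, the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. For medians over genes, the standard error comes from resampling the genes, which are not independent, and leaves out the spread between libraries. CPM values are given as mean ± SD of 5 libraries, scaled within the libraries compared, so that a vehicle value differs slightly between comparisons. For log CPM a prior count of 2 was used.

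Gene lists, 40 in all, covering skeletal cells, signalling, metabolism, stress, cell cycle and the other cell types a limb bud holds, were fixed before the data were examined, and so were the tests, their alternatives and the rule for named genes. They were tested against the other genes with camera (limma 3.58.1) with a preset correlation of 0.01, and again with the correlation estimated from the libraries, with adjustment over the 40 lists. Fry, which asks whether a list's genes move on balance in a direction without comparing them with other genes, was an alternative. The text names, per comparison, up to 8 protein-coding genes with the largest rise and 8 with the largest fall (mean count of at least 50, groups not overlapping), up to 4 called members of smallest p from each list that passed camera or had at least 25% and 3 members called, a fixed set of skeletal, sterol, receptor and cell-cycle genes, and the 5 genes of smallest p in each test between doses or between times. Which of the genes allowed by that rule appear was chosen with their values in view, and 2 genes outside it are said to be so. Results of some genes are not reported here.

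Alternatives were DESeq2 1.42.0, median-of-ratios and upper-quartile factors, no filter on low counts, a stricter filter (1 CPM in 5 libraries), all 45 libraries in 1 fit or only the groups compared, the replicate number as a block, each library left out in turn, and a threshold of 0.01 for overlaps. Chosen after seeing the data was a fit with the mean log expression of epidermal markers as a covariate at 24 and 48 h, and so were refits with the block or the covariate on the genes kept without them, since the filter on low counts keeps more genes with either in the design. Replicate numbers are shared between groups, and whether they pair libraries was judged by the correlation of same-numbered libraries' deviations from their group means, with every pair over 0.1 taken as pairing. That held for 10 µM against vehicle at 24 h (0.107 to 0.459) and 48 h (0.154 to 0.505), for 50 µM against vehicle at 48 h (0.151 to 0.317) and, with the numbers in the library codes, for 50 against 10 µM at 48 h (0.149 to 0.366). The pairing comes from the data, since the labels do not say what a number marks. Camera with an estimated correlation was run only without the block, also for the comparisons that the numbers pair.

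The fitting steps were tested on simulated counts with 200 genes changed by known folds, drawn from the real means, library sizes and trend of spread with expression. The draws hold no spread particular to a gene, no structure by replicate number and no outlying library. They may therefore overstate recovery in the real data. With 50 µM at 3 h, 95.5% of genes changed 4-fold were recovered, at 24 h 100% and at 48 h 90.9%. For unchanged groups that share controls, 10 simulations were run per time. Tables were joined with pandas 2.3.3 in Python 3.11.15 and plotted with matplotlib 3.10.9.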

Results

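RNA was sequenced from forelimb buds of mouse embryos kept in organ culture with bisphenol A, a plastics monomer that binds estrogen receptors. The limb buds came from CD1 embryos, an outbred stock, on gestation day 13, when the cartilage models of the limb bones are laid down. Limbs of male and female embryos were cultured together in medium with vehicle (dimethyl sulfoxide) or with 10 or 50 µM bisphenol A, and RNA was taken after 3, 24 or 48 h. The 9 groups of 5 libraries each gave 45 libraries, all of which were assigned by their labels. The title of the series names endochondral ossification, the replacement of cartilage by bone, as the process under study. Each library held between 17.54 and 27.12 M counts (M for mega) in genes, and group means lay between 19.56 and 22.94 M counts. The labels do not say whether the 5 libraries of a group came from separate litters or culture days, so p-values measure the spread between these libraries, which may in part be technical.

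Culture time was the main difference between libraries. The first principal component of log2 CPM (counts scaled to library size) took 27.5% of the variance and ordered the libraries by hours in culture, and the second took 7.05%. Along the second component the libraries differed in epidermal transcripts. Krt14, a keratin of the basal epidermis, ranged from 2.97 to 445 CPM over the 45 libraries, with 148 ± 181 CPM (mean ± SD, n = 5) in vehicle at 24 h and 142 ± 44.6 CPM with 50 µM at 24 h. Skeletal muscle transcripts took 0.738 ± 0.129% of the counts in vehicle at 48 h and 0.359 ± 0.0637% with 50 µM. Between libraries of the same group, counts differed by more than sampling noise in every pair, with a chi-square per degree of freedom from 6.07 to 56.6, which argues against a library deposited more than once in a group and does not show that they came from separate cultures.

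**Figure D1:**
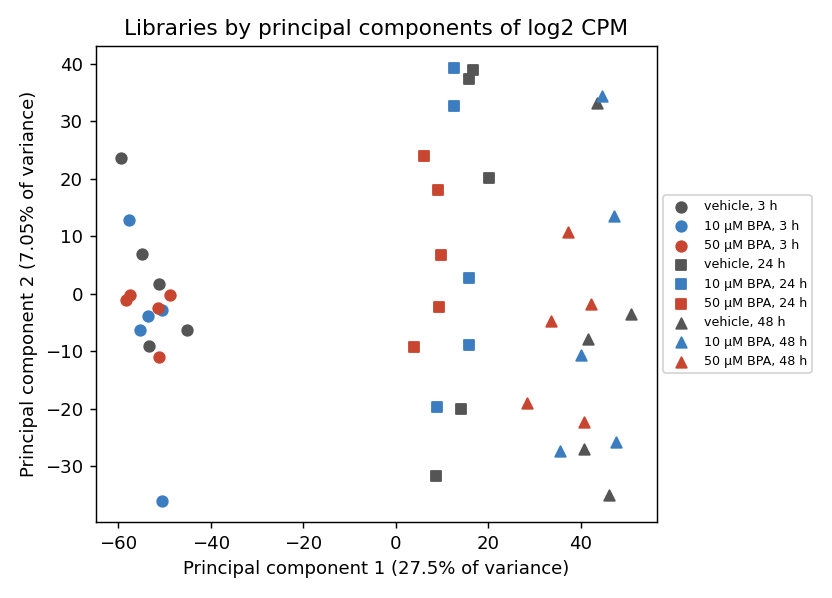
Principal components 1 (27.5% of the variance) and 2 (7.05%) of log2 CPM, in component units without a physical scale, with each point a library, colour for dose (grey vehicle, blue 10 µM, red 50 µM) and shape for culture time (circle 3 h, square 24 h, triangle 48 h). Libraries of 3 h lie at the left, of 24 h in the middle and of 48 h at the right, and a 10 µM library of 3 h lies below the other libraries of its time.

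The vehicle groups show how the limb buds changed in culture without bisphenol A. Between 3 and 24 h, genes of cartilage and bone rose together. Col2a1, the main collagen of cartilage, rose 2.58-fold from 2509 ± 280 to 6462 ± 425 CPM, and Acan, the main cartilage proteoglycan, rose 2.87-fold. Col10a1, the collagen of hypertrophic cartilage, rose 9.98-fold, and Ibsp, a mineral-binding protein of bone and hypertrophic cartilage, rose 104-fold from 1.76 ± 1.72 CPM. Of the measured members, 23 of 25 rose in the chondrocyte matrix list (24 adjusted over the list alone), 17 of 21 in the prehypertrophic and hypertrophic chondrocyte list (18 adjusted over the list alone) and 16 of 22 in the osteoblast list (16 adjusted over the list alone), while 1 osteoblast gene fell. Sp7 and Alpl, a transcription factor and the phosphatase of mineralising cells, rose 2.47-fold and 3.21-fold, and Ihh, a signal of prehypertrophic chondrocytes, rose 1.99-fold. Sox9, the regulator of early cartilage, was not called, at -0.14 ± 0.08 (log2 fold change ± SE).

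Other cell types and processes moved over the same hours. Muscle genes rose, 27 of 29 measured members (28 adjusted over the list alone), among them Acta1 and Tnnt2, genes of the contractile apparatus, at 4.22-fold and 4.02-fold. Macrophage genes rose in 13 of 20 cases (14 adjusted over the list alone), with Lyz2, the macrophage lysozyme, at 44.2 ± 9.16 CPM against 3.67 ± 0.823 at 3 h, and Gpnmb, a glycoprotein of macrophages and bone cells, rose 36.7-fold. All 30 genes of the G2/M list fell (30 adjusted over the list alone), with Cenpe and Tpx2, which serve mitosis, and Mki67, a marker of dividing cells, 2.61-, 2.31- and 2.19-fold lower. The DNA replication list held 30 of 32 members that fell (31 adjusted over the list alone). Limb bud patterning genes fell in 26 of 37 cases (28 adjusted over the list alone), for example Lhx9 and Msx1 with log2 fold changes of -1.33 ± 0.09 and -1.11 ± 0.12. Endothelial genes fell in 12 of 17 cases (14 adjusted over the list alone), with Plvap at -2.65 ± 0.14, and erythroid genes in 8 of 13 (10 adjusted over the list alone), with Slc4a1 at -1.88 ± 0.17. Aplnr, a receptor of venous endothelium, fell 5.92-fold and Cyp1a1, a target of the aryl hydrocarbon receptor, fell 6.70-fold. Fmod, a tendon matrix protein, rose 2.44-fold and Cdkn1a, a cell-cycle inhibitor, 2.14-fold. In all, edgeR called 5131 of 17081 genes, 2781 higher and 2350 lower. With a preset correlation each of these lists passed camera, and with an estimated correlation the muscle list (adjusted p = 0.0726 with an estimated correlation) and the erythroid list (adjusted p = 0.0726 with an estimated correlation) did not.

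Between 24 and 48 h in vehicle, members of the cartilage and bone lists rose further, and of 30 G2/M genes 1 rose and none fell. Ibsp rose 3.50-fold to 640 ± 206 CPM, Col10a1 3.19-fold, Spp1, a bone matrix phosphoprotein, 2.73-fold, and Col1a1, the main collagen of bone and tendon, 2.30-fold. Members rose in 17 of 25 cases in the chondrocyte list (20 adjusted over the list alone), with Comp and Acan 2.26-fold and 1.67-fold higher, in 8 of 22 in the hypertrophic list (12 adjusted over the list alone), in 13 of 22 in the osteoblast list (14 adjusted over the list alone), with Sp7 1.60-fold higher, and in 14 of 24 in the tendon list (15 adjusted over the list alone), where 1 fell. Tnmd and Bgn, a membrane protein and a proteoglycan of tendon, rose 2.42-fold and 2.14-fold. Targets of p53 rose in 16 of 26 cases (17 adjusted over the list alone), with Eda2r, a death receptor, 5.42-fold and Cdkn1a 2.15-fold higher. Immediate early genes rose in 14 of 28 cases (16 adjusted over the list alone), with Arc and Egr3 7.53-fold and 6.48-fold higher. The inflammatory list had 5 of 20 members that rose (7 adjusted over the list alone), Ptgs2 and Ccl2 among them at 6.05-fold and 6.94-fold. Erythroid genes fell in 8 of 10 cases (8 adjusted over the list alone), with Hbb-bt and Slc4a1 3.72-fold and 3.31-fold lower. Cholesterol synthesis genes fell in 12 of 26 cases (16 adjusted over the list alone), with Fdft1 and Hmgcs1, enzymes of the pathway, at -0.38 ± 0.06 and -0.28 ± 0.06, and limb patterning genes in 14 of 35 (19 adjusted over the list alone), with Hoxd13 at -0.47 ± 0.07. Mki67 was not called, at 0.13 ± 0.07. The p53, osteoblast, hypertrophic, tendon, patterning and erythroid lists also passed camera with an estimated correlation. The chondrocyte list (adjusted p = 0.105 with an estimated correlation), the cholesterol list (adjusted p = 0.127 with an estimated correlation), and the immediate early and inflammatory lists (adjusted p = 0.269 with an estimated correlation for both) did not. Of 16940 genes, 1432 were called, 921 higher and 511 lower.

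Over the whole culture, from 3 to 48 h in vehicle, 7901 of 16905 genes were called, 4036 higher and 3865 lower. Ibsp was 364-fold, Col10a1 31.8-fold, Spp1 19.4-fold, Alpl 6.19-fold, Acan 4.80-fold, Col1a1 4.39-fold, Sp7 3.97-fold and Col2a1 3.93-fold higher at 48 h. All 22 measured members of the hypertrophic list rose (22 adjusted over the list alone), as did 24 of 25 of the chondrocyte list and 19 of 22 of the osteoblast list, with the same counts adjusted over the list alone. Muscle genes rose in 27 of 29 cases (27 adjusted over the list alone), with Acta1 and Tnnt3, a fast troponin, 6.17-fold and 5.91-fold higher, and macrophage genes in 15 of 20 (15 adjusted over the list alone), with Lyz2 26.2-fold higher. Eda2r was 11.5-fold and Cdkn1a 4.61-fold higher. Limb patterning genes fell in 32 of 36 cases (33 adjusted over the list alone), with Msx2 5.94-fold lower, and G2/M genes in 30 of 30 (30 adjusted over the list alone), with Mki67 2.00-fold lower. Stra6, a retinol transporter, was 5.91-fold, Aplnr 15.7-fold, Plvap 7.54-fold and Cyp1a1 7.71-fold lower. With an estimated correlation, camera still called the chondrocyte, hypertrophic, osteoblast, patterning and G2/M lists, but not the muscle list (adjusted p = 0.0772 with an estimated correlation) or the macrophage list (adjusted p = 0.146 with an estimated correlation).

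What bisphenol A changed within hours was read from the 3 h groups at 50 µM, where genes of cholesterol synthesis rose together. Of 26 measured members of the cholesterol synthesis and uptake list, 22 rose and none fell (23 adjusted over the list alone), with a median log2 fold change of 0.75. Dhcr7, an enzyme of the last steps of cholesterol synthesis, went from 50.4 ± 3.02 to 112 ± 7.76 CPM (mean ± SD, n = 5). Cyp51, which removes a methyl group from lanosterol, rose by 1.03 ± 0.07 (log2 fold change ± SE), Insig1, a sterol-regulated protein of the endoplasmic reticulum, by 1.10 ± 0.09, and Idi1 by 1.01 ± 0.08. Hmgcs1 (chromosome 13, 119690379 to 119708260 in mm10) and Sqle rose 1.66-fold and 1.81-fold. Of 16 fatty acid synthesis genes, 7 rose (12 adjusted over the list alone), led by Scd1, a stearoyl-CoA desaturase, at 2.32-fold, with Scd2, Fads1 and Fads2, further desaturases, at 1.41-, 1.37- and 1.54-fold.

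Genes of the endoplasmic reticulum also rose at 3 h, 13 of 20 chaperone genes (17 adjusted over the list alone). Derl3, a factor of protein disposal from the endoplasmic reticulum, rose 2.57-fold, and Hspa5, Calr and Xbp1 rose 1.49-, 1.47- and 1.42-fold. In the integrated stress response list, 3 of 30 members rose (16 adjusted over the list alone), among them Slc7a5, an amino acid transporter, at 1.46-fold and Ddit3, a stress-induced transcription factor, at 1.48-fold. Of the list for bone morphogenetic protein (BMP) and TGF-beta, 6 of 34 rose and 1 fell (10 and 2 adjusted over the list alone), with the BMP targets Id1, Id3 and Smad6 1.82-, 1.75- and 1.41-fold higher. Rarb, Cyp26a1 and Cyp26b1, which respond to retinoic acid, rose 1.62-, 1.90- and 1.41-fold, the 3 called members of 20 in the retinoic acid list (4 higher and 2 lower adjusted over the list alone). Of 15 mitochondrially encoded transcripts, 2 rose and 4 fell (2 and 7 adjusted over the list alone), with mt-Rnr1, the small ribosomal RNA, 2.13-fold higher at 870 ± 125 CPM and mt-Cytb and mt-Nd6 at -0.49 ± 0.07 and -0.57 ± 0.09. Hhip, an antagonist and target of Hedgehog, Abcg1, a sterol exporter, Cx3cr1, a chemokine receptor of macrophages, and Ankrd37 fell 1.88-, 1.72-, 1.71- and 2.24-fold. Klf2 was lower at -0.84 ± 0.16, and Eif2s3y, a Y-linked gene, was 1.66-fold lower, in libraries that also held less of the Y-linked Ddx3y (43.59 ± 16.31 against 72.46 ± 10.8 CPM) and more of the X-linked Xist (815.2 ± 389.1 against 524.5 ± 107.3 CPM). Among the genes chosen after their values were seen, Tuba1a, an alpha-tubulin, fell by 0.59 and Srsf3, a splicing factor, fell by 0.49 on the log2 scale. The cartilage genes Sox9, Col2a1, Acan, Col10a1, Ihh and Runx2 were not called, with log2 fold changes of -0.14 ± 0.08, 0.02 ± 0.07, 0.04 ± 0.11, -0.20 ± 0.23, 0.31 ± 0.10 and -0.41 ± 0.11. Neither were the estrogen receptor genes Esr1 and Esr2, at 1.45 ± 0.415 and 0.662 ± 0.122 CPM in vehicle, nor Cyp1a1 and Cyp1b1, targets of the aryl hydrocarbon receptor, at -0.30 ± 0.26 and 0.05 ± 0.23.

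In total, 239 of 16988 genes were called at 3 h with 50 µM (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), 151 higher and 88 lower, and DESeq2 called 574. Among the strongest was Dhcr7, with an edgeR adjusted p of 1.09e-07 and a higher value in each of the 5 treated libraries than in any vehicle library. By camera, 12 of 40 lists passed, and the cholesterol list (camera adjusted p = 1.92e-59), the chaperone list and the fatty acid list also passed with an estimated correlation, at adjusted p = 0.000841, 0.00209 and 0.0205. The calls of the stress response list (adjusted p = 0.0763 with an estimated correlation), the BMP list (adjusted p = 0.117 with an estimated correlation), the retinoic acid list (adjusted p = 0.333 with an estimated correlation) and the mitochondrial list (adjusted p = 0.51 with an estimated correlation) were among those lost. In simulated data of this comparison, 56.7% of genes changed 1.5-fold and 76.1% of those changed 2-fold were recovered. The count fell to 151 without vehicle replicate 1, 141 without vehicle replicate 3, and 145, 156, 155 and 144 without 50 µM replicates 1, 2, 4 and 5, and Cyp26a1, Ankrd37 and Eif2s3y lost their calls in 8, 8 and 4 of the 10 fits that each left out a library.

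**Figure D2:**
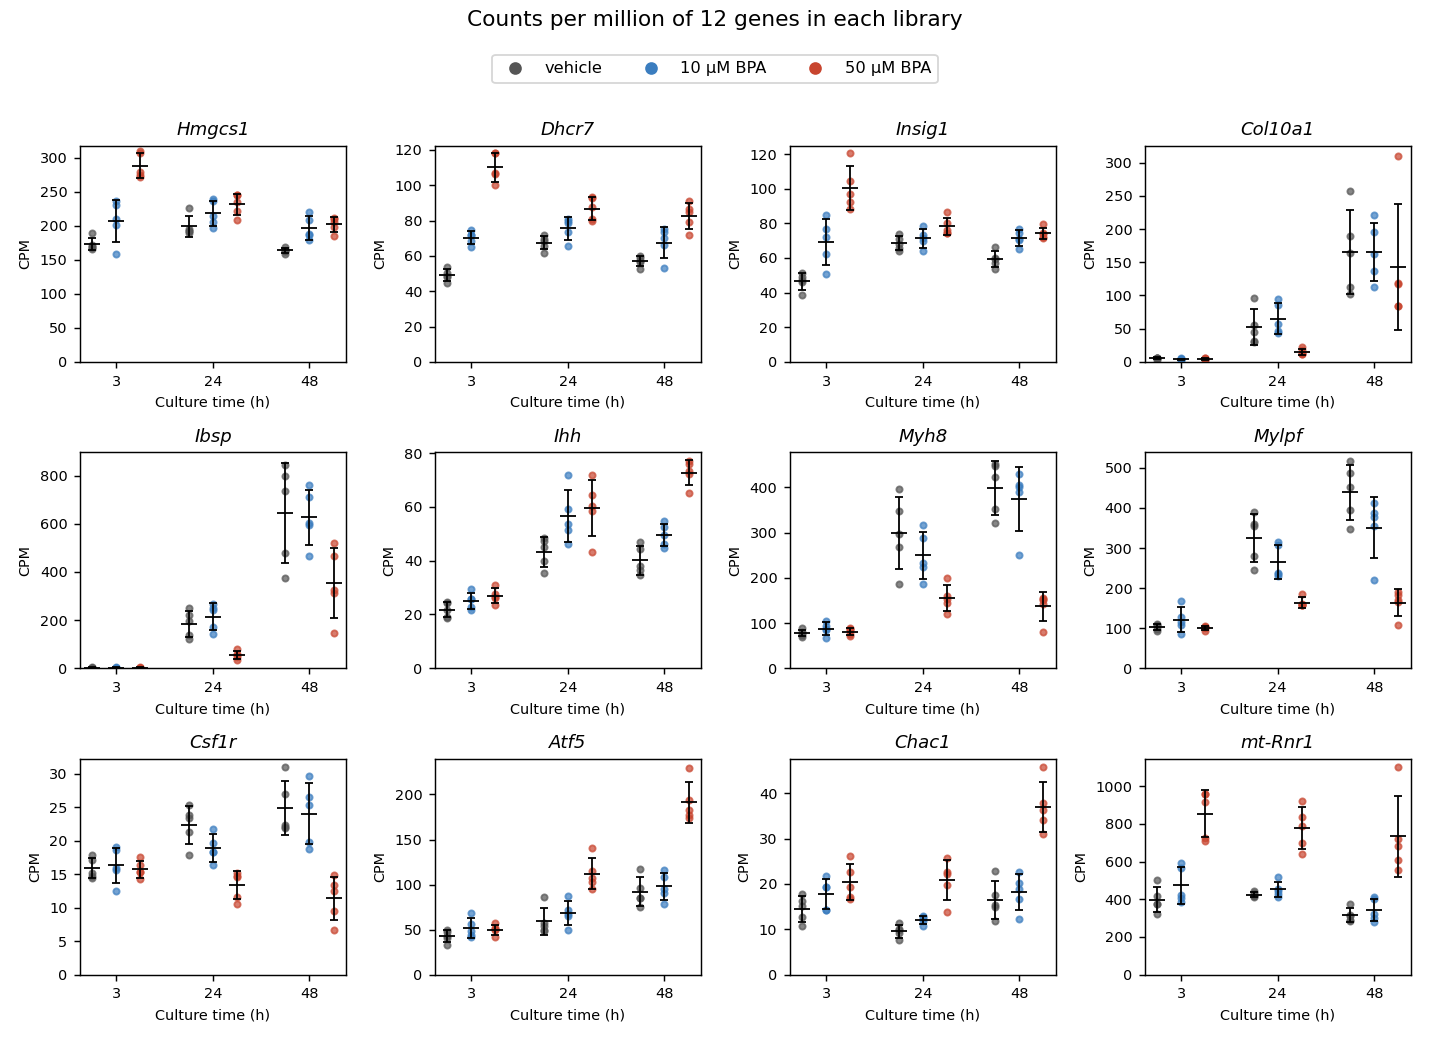
CPM (vertical axes, from 0) of 12 genes at 3, 24 and 48 h of culture (horizontal axes), with each dot a library, grey for vehicle, blue for 10 µM and red for 50 µM, and black bars for the mean ± SD of 5 libraries. Hmgcs1 with 50 µM stands above vehicle at 3 h (means of 289 and 173 CPM), Col10a1 and Ibsp rise with time, and the means of Mylpf with 50 µM lie below those of vehicle at 24 h (164 against 326 CPM) and 48 h (164 against 440 CPM). With 10 µM at 3 h the means of Dhcr7 (70.4 against 49.2 CPM) and Insig1 (69.3 against 46.5 CPM) also lie above vehicle.

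After 24 h with 50 µM, Col10a1 and Ibsp, genes of late cartilage and bone, and 16 of 29 muscle genes were lower than in vehicle, and 15 of 30 genes of the integrated stress response were higher. Col10a1 (chromosome 10, 34389981 to 34397085 in mm10) was at 15.3 ± 4.62 CPM against 52.1 ± 27.3 in vehicle (mean ± SD, n = 5), 3.38-fold lower, and Ibsp (chromosome 5, 104299171 to 104311469) at 55.7 ± 16.7 against 185 ± 55.2, 3.32-fold lower. Ihh rose 1.38-fold, so that the hypertrophic chondrocyte list of 22 genes had 1 that rose and 2 that fell (1 and 3 adjusted over the list alone). In the osteoblast list 2 of 22 fell (5 adjusted over the list alone), and Runx2, Sp7, Col1a1, Spp1 and Alpl were not called, at -0.19 ± 0.10, -0.16 ± 0.10, -0.23 ± 0.07, -0.79 ± 0.30 and -0.35 ± 0.09 (log2 fold change ± SE). The early cartilage genes Sox9, Col2a1 and Acan were not called either, at 0.23 ± 0.07, 0.08 ± 0.06 and 0.09 ± 0.08, and in the chondrocyte list 2 of 25 rose and 2 fell. With the replicate number, which does not pair all of these libraries, as a block on the same genes, Sox9, Col1a1, Alpl and Spp1 were called (adjusted p = 0.0157, 0.0167, 0.0304 and 0.00162), and with the epidermal covariate Sox9, Col1a1 and Alpl (adjusted p = 0.0207, 0.0415 and 0.0387) but not Spp1 (adjusted p = 0.234).

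Muscle genes fell in 16 of 29 cases at 24 h (22 adjusted over the list alone), with a median log2 fold change of -0.62. Mylpf, Tnnt3 and Tnnc1, of the contractile apparatus, fell 1.99-, 2.09- and 1.77-fold, and Csrp3 and Casq1, further muscle genes outside the list, fell 3.26-fold and 2.98-fold. Fgf6, a growth factor of the myogenic lineage, fell 3.55-fold. Muscle transcripts took 0.603 ± 0.124% of counts in vehicle and 0.375 ± 0.0406% with 50 µM, and macrophage transcripts 0.0272 ± 0.00201% and 0.0203 ± 0.000761%. The macrophage list had 4 of 20 members that fell (8 adjusted over the list alone), among them Csf1r and C1qa at 1.68-fold and 1.58-fold, and the tendon list 6 of 24 (9 lower and 1 higher adjusted over the list alone), among them Tnmd, Fmod and Bgn at 2.06-, 1.31- and 1.29-fold. Of 30 G2/M genes, 4 fell (20 adjusted over the list alone), with Top2a and Nusap1 at -0.28 ± 0.06 and -0.44 ± 0.09, while Mki67 was not called at -0.28 ± 0.08 but was with the block (adjusted p = 0.00772) and with the epidermal covariate (adjusted p = 0.0463). PPAR targets fell in 6 of 18 cases (6 lower and 1 higher adjusted over the list alone), with Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, 2.06-fold lower, and Cd36, Angptl4 and Lpl, of lipid uptake, 1.91-, 1.68- and 1.51-fold lower.

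At 24 h, part of the stress lists rose. In the integrated stress response list 15 of 30 rose (15 adjusted over the list alone), with Chac1, Atf5, Slc7a5 and Asns 2.17-, 1.90-, 1.60- and 1.48-fold higher, and in the chaperone list 10 of 20 (20 adjusted over the list alone), with Derl3 3.56-fold, Calr 1.35-fold and Hspa5 1.31-fold higher. Cholesterol synthesis genes rose in 5 of 26 cases (10 adjusted over the list alone), with Dhcr7 and Cyp51 1.29-fold and 1.25-fold higher, and Hmgcs1 was not called at 0.22 ± 0.07. In the fatty acid list 2 of 16 rose. The BMP and TGF-beta list had 10 of 34 members that rose and 3 that fell (11 and 4 adjusted over the list alone), including Id2 and Bambi at 1.40-fold and 1.32-fold higher. In the retinoic acid list 6 of 19 rose and 1 fell (8 and 2 adjusted over the list alone), with Rarb and Cyp26a1 1.92-fold and 2.20-fold higher and Aldh1a3, which makes retinoic acid, 2.04-fold lower. Cyp1a1 and Cyp1b1 rose 2.07-fold and 1.85-fold, Cdkn1a fell by 0.35 ± 0.08 on the log2 scale, and mt-Rnr1 rose 1.83-fold while mt-Cytb and mt-Nd6 fell by 0.46 ± 0.08 and by 0.52 ± 0.11.

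The 24 h comparison called 585 of 16841 genes with 50 µM, 231 higher and 354 lower, and DESeq2 called 994 and edgeR with the replicate number as a block 1146. The edgeR adjusted p was 0.00375 for Col10a1 and 0.000551 for Ibsp, each of which was lower in all 5 treated libraries than in any vehicle library. Camera called 20 of 40 lists, and with an estimated correlation the chaperone list (adjusted p = 0.0363 with an estimated correlation) and the macrophage list (adjusted p = 0.0405 with an estimated correlation) held. The muscle, G2/M and tendon lists (adjusted p = 0.152 with an estimated correlation for each) were among those whose call was lost. So were the stress response list (adjusted p = 0.0587 with an estimated correlation), the cholesterol list (adjusted p = 0.174 with an estimated correlation), the BMP and hypertrophic lists (adjusted p = 0.173 with an estimated correlation for both), the PPAR list (adjusted p = 0.281 with an estimated correlation), the retinoic acid list (adjusted p = 0.292 with an estimated correlation) and the osteoblast list (adjusted p = 0.332 with an estimated correlation). In simulated data of this comparison 55.2% of genes changed 1.5-fold were recovered. The count was 351, 366 and 362 without vehicle replicates 3, 4 and 5, and 351, 345 and 365 without 50 µM replicates 2, 4 and 5. Ihh, Cyp26a1, Lpl, Cdkn1a, Cyp1a1, Angptl4, Cd36, Fmod and Top2a lost their calls in 8, 7, 6, 5, 5, 4, 3, 3 and 1 of the 10 fits that each left out a library, and C1qa and Bgn did so when all 45 libraries shared 1 fit.

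After 48 h with 50 µM, muscle genes were lower than in vehicle, 24 of 29 measured members (25 adjusted over the list alone), with a median log2 fold change of -0.96. Myh8, a myosin of developing muscle, fell from 389 ± 57.2 to 133 ± 30.8 CPM (mean ± SD, n = 5), and Mylpf, Myl1 and Tnnc1 fell 2.70-, 2.39- and 2.32-fold. Outside the list, Myh7b (chromosome 2, 155611212 to 155634307 in mm10), a slow myosin gene, fell 4.64-fold, and Csrp3, Atp1b4 and Fgf6, which muscle expresses, fell 5.93-, 6.29- and 3.96-fold. Macrophage genes fell in 6 of 19 cases (9 adjusted over the list alone), with Csf1r, C1qa and Cx3cr1 2.19-, 1.98- and 2.08-fold lower, and tendon genes in 8 of 24 (9 adjusted over the list alone), with Tnmd and Fmod 2.24-fold and 1.57-fold lower. Macrophage transcripts took 0.0387 ± 0.00476% of counts in vehicle and 0.0269 ± 0.00635% with 50 µM. Acta2, the smooth muscle actin, fell 2.00-fold, and 3 of 11 members of the pericyte and smooth muscle list fell. That list did not pass camera (adjusted p = 0.13) but passed with the replicate number as a block (adjusted p = 0.0205). Its adjusted p with an estimated correlation was 0.445.

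The skeletal genes moved in different directions at 48 h. Fgfr3 (chromosome 5, 33721674 to 33737068 in mm10), a growth factor receptor of chondrocytes, rose 1.92-fold from 217 ± 22.7 to 418 ± 28.2 CPM, Xylt1, which starts the sugar chains of proteoglycans, rose 1.49-fold, Sox9 1.18-fold and Ihh by 0.85 ± 0.08 on the log2 scale, while Ucma, a cartilage matrix protein, fell 5.35-fold. Of 25 chondrocyte genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone), and Col2a1 and Acan were not called at 0.28 ± 0.09 and 0.29 ± 0.10 (log2 fold change ± SE). Col10a1 and Ibsp, lower at 24 h, were not called at 48 h, with -0.22 ± 0.32 and -0.88 ± 0.28, and the difference between the effects at the 2 times was not called for either. With the replicate number, which pairs these libraries, as a block on the same genes, Ibsp (adjusted p = 0.00349), Col2a1 (adjusted p = 0.00045) and Acan (adjusted p = 0.000377) were called and Col10a1 (adjusted p = 0.221) was not. With the epidermal covariate Ibsp was called (adjusted p = 0.0399), and Col2a1, Acan and Col10a1 were not (adjusted p = 0.0801, 0.0769 and 0.681). The hypertrophic list had 2 of 22 members that rose and 3 that fell, and the osteoblast list 3 of 22 that rose and 4 that fell, with Col1a1 and Col1a2 at -0.38 ± 0.11 and -0.35 ± 0.09. Runx2, Sp7, Spp1 and Alpl were not called, at -0.01 ± 0.08, -0.07 ± 0.14, 0.22 ± 0.28 and 0.08 ± 0.13. Gdf5, a signal of joint formation, rose 1.63-fold, and the joint list had 4 of 16 that rose and 4 that fell.

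Members of the stress response, chaperone and cholesterol lists rose at 48 h, though no call of these lists held with an estimated correlation. In the integrated stress response list 20 of 30 rose (27 adjusted over the list alone), with Cth, Trib3, Chac1 and Atf5 2.76-, 2.53-, 2.23- and 2.07-fold and the amino acid transporter genes Slc7a5 and Slc3a2 1.88-fold and 1.51-fold higher, and Adm2, outside the list, 2.68-fold higher. Chaperone genes rose in 13 of 20 cases (19 adjusted over the list alone), with Derl3, Herpud1 and Calr 2.44-, 1.43- and 1.29-fold higher. Cholesterol genes rose in 14 of 26 (17 adjusted over the list alone), with Msmo1, Dhcr7, Cyp51, Hmgcs1 and Sqle 1.48-, 1.44-, 1.39-, 1.23- and 1.22-fold higher. The fatty acid list had 9 of 16 that rose and 1 that fell (9 and 1 adjusted over the list alone), with Scd1 1.45-fold higher, and the sterol efflux and LXR list 2 of 13 that rose and 4 that fell, among them Abcg1, Abca1 and Apoe, of cholesterol export, at -1.43 ± 0.13, -0.39 ± 0.05 and -0.66 ± 0.11. NRF2 targets rose in 7 of 24 cases and 1 fell (10 and 1 adjusted over the list alone), with Gsta4 and Hmox1 1.61-fold and 1.47-fold higher. In the BMP list 10 of 34 rose and 1 fell (13 and 6 adjusted over the list alone), with Bambi 1.44-fold higher. In the retinoic acid list 6 of 19 rose and 4 fell, with Rarb 2.24-fold higher and Aldh1a3 and Aldh1a2, which make retinoic acid, 2.80-fold and 1.85-fold lower. Cyp1b1 rose 1.61-fold and Gper1, a membrane receptor for estrogen, fell 1.63-fold. Cdkn1a and Mki67 were not called, at -0.10 ± 0.12 and -0.08 ± 0.09. Of the mitochondrial transcripts, mt-Rnr1, mt-Rnr2 and mt-Co1 rose 2.31-, 1.60- and 1.37-fold and mt-Nd6 fell 1.38-fold. In the nuclear-encoded respiratory chain list 4 of 32 fell (9 adjusted over the list alone).

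At 48 h with 50 µM, 1536 of 16732 genes were called, 650 higher and 886 lower, and the same test with the replicate number as a block called 2583. The edgeR adjusted p was 8.73e-06 for Myh7b and 5e-06 for Fgfr3, and the 5 treated libraries lay apart from the 5 vehicle libraries for both. By camera 14 of 40 lists passed, and only the fatty acid list held with an estimated correlation (adjusted p = 0.0439), in a fit that left the pairing out. The calls of the chaperone and BMP lists (adjusted p = 0.0552 with an estimated correlation for both), the stress response and cholesterol lists (adjusted p = 0.0935 with an estimated correlation for both), the muscle list (adjusted p = 0.108 with an estimated correlation) and the tendon list (adjusted p = 0.116 with an estimated correlation) were among those lost. The same held for the respiratory chain list (adjusted p = 0.224 with an estimated correlation), the NRF2 list (adjusted p = 0.312 with an estimated correlation), the macrophage list (adjusted p = 0.463 with an estimated correlation) and the chondrocyte list (adjusted p = 0.618 with an estimated correlation). The hypertrophic, osteoblast, retinoic acid and sterol efflux lists did not pass camera, at adjusted p = 0.988, 0.939, 0.561 and 0.142. In simulated data of this comparison 67.2% of genes changed 1.5-fold were recovered, and Col1a1, Col1a2 and Sox9 lost their calls in 7, 6 and 5 of the 10 fits that each left out a library, while Abca1 and Gper1 did so when all 45 libraries shared 1 fit.

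**Figure D3:**
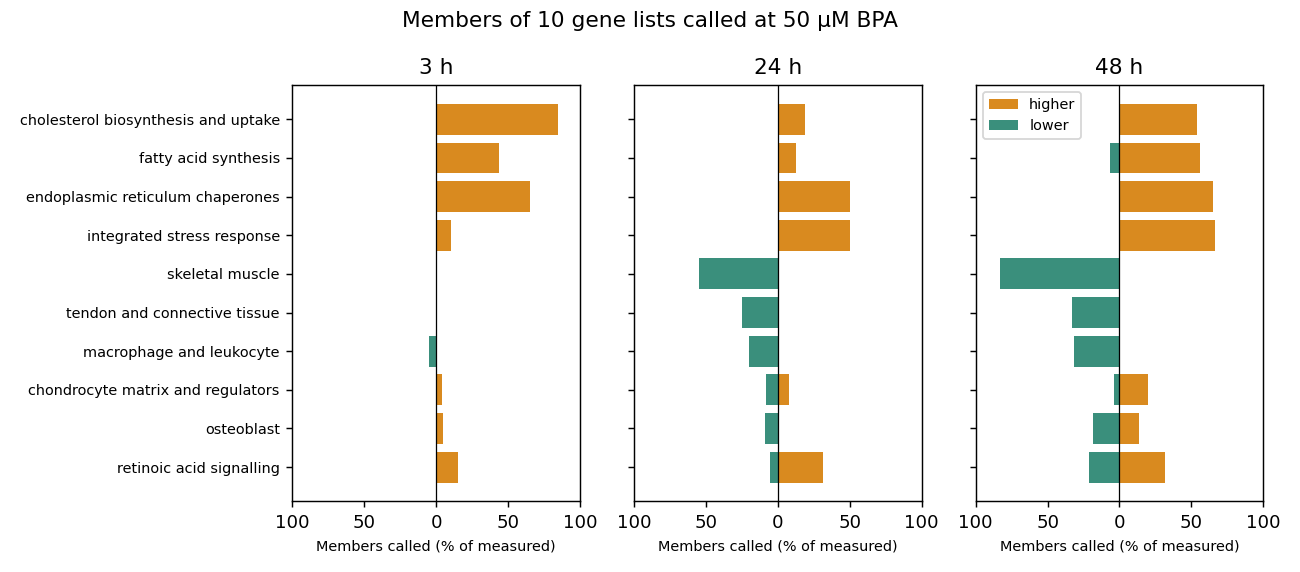
Share of the measured members of 10 gene lists that edgeR called at 50 µM against vehicle, in percent on the horizontal axis (orange to the right for higher, green to the left for lower), with a panel for each of 3, 24 and 48 h. The cholesterol bar is longest at 3 h (22 of 26 members higher) and the muscle bar at 48 h (24 of 29 members lower).

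Whether the response to 50 µM changed with time was tested as an interaction in the fit of all 45 libraries. Among the smallest p-values were genes of cholesterol synthesis with a smaller effect at 24 h than at 3 h, with differences in log2 fold change (± SE) of -0.78 ± 0.10 for Fdft1, -0.90 ± 0.12 for Nsdhl, -0.80 ± 0.10 for Dhcr7 and -0.72 ± 0.09 for Cyp51, all enzymes of the pathway. This test called 122 of 19247 genes, 20 with a higher and 102 with a lower effect at 24 h, and DESeq2 called 218. Of 50 splits of the libraries, the real one counted, 4 called as many genes. Such splits do not keep an equal effect at both times, so chance is not excluded for this count. No list was tested for the difference. Between 48 and 3 h, 375 genes differed, 67 with a higher and 308 with a lower effect at 48 h. Muscle genes stood among the smallest p-values, with differences of -2.17 ± 0.25 for Myh7b, -1.88 ± 0.24 for Apobec2 and -1.59 ± 0.20 for Myh3, together with AW551984 at -1.21 ± 0.15 and Glt8d2 at -1.18 ± 0.15. Between 48 and 24 h the edgeR interaction test called 0 genes, with 645 at an unadjusted p under 0.05, where 962 are expected by chance, and 4 called by DESeq2. The smallest p-values there belonged to Myh7b, Tubb5, Pctp, Bdnf and Myf5, with differences of -1.23 ± 0.25, 0.38 ± 0.08, -1.32 ± 0.29, -1.09 ± 0.27 and -1.02 ± 0.25. It called 2 genes without 50 µM replicate 5 of 24 h, 2 without 50 µM replicate 2 of 48 h and 1 without 50 µM replicate 3 of 48 h.

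The comparisons of 50 µM with vehicle at the 3 times share no library, and their calls overlapped. At 3 and 24 h, 59 genes were higher and 23 lower at both, where lists drawn independently would share 2.13 and 1.86, and 0 went in opposite directions. For 24 and 48 h the overlap was 171 higher and 267 lower, against 9.16 and 18.7, again with 0 in opposite directions, and for 3 and 48 h it was 84 higher and 25 lower, against 6.03 and 4.6, with 5 in opposite directions. At all 3 times, 53 genes were higher and 17 lower.

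At 10 µM, the lower dose, the sterol genes Sqle and Hmgcs1 had small positive fold changes and few genes passed the test. At 3 h, Sqle and Hmgcs1 were not called, with log2 fold changes of 0.40 ± 0.09 and 0.25 ± 0.10 (± SE, n = 5 per group). Adjusted over the list alone, 16 of 26 cholesterol genes and 8 of 20 chaperone genes rose, where 0 of both rose over all genes tested. Both lists passed camera (adjusted p = 1.08e-21 and 4.71e-08) and held with an estimated correlation (adjusted p = 0.0209 and 0.0417). The stress response list had 2 members that rose adjusted over the list alone, and it and the fatty acid list passed camera but not with an estimated correlation (adjusted p = 0.263 and 0.0815 with an estimated correlation). Col10a1, Ihh and Sox9 were not called, at -0.34 ± 0.22, 0.20 ± 0.11 and -0.20 ± 0.10. Over all 17009 genes edgeR called 0, with 974 at an unadjusted p under 0.05 against 850 expected by chance, and DESeq2 called 16. Without 10 µM replicate 3, 5 genes were called. That library stood apart from its group, with a chi-square per degree of freedom of 30.4 to 56.6 against each other library. The other pairs of the group had 6.63 to 12.6. Over all genes the fold changes of this comparison fell with gene length (Spearman's rho of -0.329, genes not being independent), and the list tests were not corrected for length.

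At 24 h with 10 µM, edgeR again called 0 of 17060 genes, with 786 at an unadjusted p under 0.05 against 853 expected by chance. DESeq2 called 17, and edgeR with the replicate number as a block 97. Col10a1 and Ibsp, lower with 50 µM, were at 0.34 ± 0.30 and 0.22 ± 0.20 with 10 µM, and Ihh, Sox9, Sqle and Hmgcs1 at 0.39 ± 0.11, 0.06 ± 0.07, 0.20 ± 0.07 and 0.14 ± 0.07. With the block on the same genes, Ihh (adjusted p = 0.00523) and Ibsp (adjusted p = 0.00979) were called, both higher. Neither was called with the epidermal covariate (adjusted p = 0.349 and 0.854). Of 20 chaperone genes, 10 rose adjusted over the list alone and 0 over all genes tested, with a median of 0.16. Camera called 19 lists and 23 with the block, and 0 of 40 held with an estimated correlation. The chaperone list had an adjusted p = 0.13 with an estimated correlation and the muscle list, with a median of -0.21, an adjusted p = 0.447 with an estimated correlation. The hypertrophic list (adjusted p = 0.118) passed only with the block, at an adjusted p of 0.00527.

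At 48 h with 10 µM, Cpt1a (chromosome 19, 3323301 to 3385732 in mm10) fell by 0.81 ± 0.11 on the log2 scale (edgeR adjusted p = 0.0432), from 72.46 ± 14.02 to 41.3 ± 3.22 CPM, and was the 1 gene called of 16925. It lost its call without vehicle replicate 2, 3 or 5 and without any of the 5 treated libraries in turn, each of which left 0 genes called. With the replicate number as a block 38 genes were called, 47 with the numbers in the library codes, 53 by DESeq2, and 980 had an unadjusted p under 0.05, against 846 expected by chance. Hmgcs1 and Sqle were not called, at 0.26 ± 0.06 and 0.21 ± 0.06 (Hmgcs1 was called with the numbers in the library codes as a block on the same genes, adjusted p = 0.0482), and 14 of 26 cholesterol genes rose adjusted over the list alone, against 0 over all genes tested. The cholesterol and chaperone lists passed camera (adjusted p = 8.58e-19 and 3.46e-12) but not with an estimated correlation (adjusted p = 0.0873 and 0.125 with an estimated correlation). Col10a1, Ibsp, Ihh and Sox9 were at 0.00 ± 0.22, -0.04 ± 0.19, 0.30 ± 0.09 and 0.04 ± 0.06. The hypertrophic list (adjusted p = 0.101), the PPAR list (adjusted p = 0.0741) and the macrophage list (adjusted p = 0.16) passed camera only with the block, at adjusted p of 0.0115, 0.0181 and 0.0233. With an estimated correlation 0 of 40 lists held. In simulated data of the 10 µM comparisons at 3, 24 and 48 h, 61.2%, 56.7% and 65.7% of genes changed 1.5-fold were recovered.

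The doses were also compared directly, in the fit of all 45 libraries over 19247 genes. At 3 h, Cyp51, Scd1 and Dhcr7 were higher with 50 than with 10 µM by 0.64 ± 0.06, 0.84 ± 0.09 and 0.64 ± 0.07 on the log2 scale, and Srsf3 was lower at -0.38 ± 0.05. At 24 h, Fgfr3 and Slc7a1, a cationic amino acid transporter, were higher 1.42-fold and 1.46-fold, and Col10a1, Casq1 and Abcg1 were lower 4.25-, 2.76- and 1.81-fold. At 48 h, the muscle genes Myh7b, Myom1, Apobec2 and Myh8 were lower 4.39-, 2.47-, 2.85- and 2.74-fold, and Ctsl, a lysosomal protease, was higher 1.36-fold. The test called 120 genes at 3 h (69 higher, 51 lower), 154 at 24 h (51 higher, 103 lower) and 605 at 48 h (192 higher, 413 lower). Fitted on the libraries of both doses alone, the 3 h count was 21, and by DESeq2 the 24 h count was 254. Leaving out 50 µM replicate 1 lowered the 3 h count to 73 and the 48 h count to 388. The 24 h count fell to 86, 65 and 88 without 10 µM replicates 2, 3 and 5, and to 101, 95 and 70 without 50 µM replicates 1, 4 and 5.

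Genes called at 50 µM mostly had the same sign at 10 µM, where both doses are compared with the same vehicle libraries. The share was 95.4% at 3 h (228 of 239), 95.9% at 24 h (560 of 584) and 91.6% at 48 h (1403 of 1532). With the vehicle libraries split between the doses, its median over 10 splits (lowest to highest) was 87.4% (74% to 92%), 83.1% (61.5% to 89.9%) and 76.3% (54.3% to 85.1%). Over all genes the correlation of the fold changes at both doses was 0.532, 0.58 and 0.528 at the 3 times, against 0.513, 0.507 and 0.512 on average in 10 simulations of unchanged groups with shared controls. Its median with split controls was 0.104 (0.031 to 0.143), 0.0788 (-0.118 to 0.131) and 0.11 (0.0174 to 0.175). Genes are not independent replicates in these correlations. The covariance was 0.033, 0.0384 and 0.0379, against 0.0249, 0.027 and 0.0239 in the simulations, so that differences of 0.00814, 0.0114 and 0.014 remained. The simulated groups hold no structure by replicate number. Such numbers pair libraries at 24 h (10 µM) and 48 h, and the expression of epidermal markers followed them at all 3 times. These differences are therefore not put down to dose alone. At 48 h Cpt1a, the 1 gene called at 10 µM, was lower at both doses, which have their vehicle libraries in common.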

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

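Of the tests that weigh explanations here, those chosen only after the result was seen were the comparison of early with other muscle genes, the comparison of endothelial with muscle genes, the median of the mitochondrial messenger RNAs, the overlap of comparisons without a common library and the median of the chondrocyte list, and the fit with an epidermal covariate was added after seeing the data. A library was singled out where its gap to the nearest of its group took more of the group's range than Dixon's limit of 0.71 for 5 libraries. That held in 33 of 584 groups of values, where chance gives about 5%.

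At 3 h, Hmgcs1 of vehicle replicate 4 stood at 197.8 CPM as scaled with the 50 µM libraries and 197 CPM as scaled with the 10 µM libraries, and Sqle of vehicle replicate 2 at 115.8 and 116.1 CPM. Also at 3 h, Fmod of vehicle replicate 4 was at 43.77 CPM and Slc4a1 of vehicle replicate 2 at 15.8 CPM, and with 50 µM Cyp26b1 of replicate 1 was at 268.1 CPM and Esr1 of replicate 4 at 2.952 CPM. At 24 h in vehicle, replicate 1 stood apart for Atf5 (86.29 CPM), Cyp26a1 (2.846 CPM), Arc (6.202 CPM) and Hmgcs1 (227.8, 228.1 and 226 CPM as scaled in 3 comparisons). Vehicle replicate 2 of 24 h stood apart for Cpt1a (108 CPM), Angptl4 (95.94 CPM) and Acan (532, 538.1 and 525.9 CPM as scaled in 3 comparisons). With 50 µM at 24 h, the values apart were Mylpf at 186.9 CPM and Cyp26a1 at 4.919 CPM in replicate 4, Angptl4 at 39.74 CPM in replicate 3 and Cdkn1a at 98.23 CPM in replicate 1. At 48 h, 50 µM replicate 1 stood apart for Csrp3 (0.2481 CPM), Myh8 (78.31 CPM) and Runx2 (50.96 CPM), and replicate 2 for Col2a1 (13820 CPM), Acan (1094 CPM) and Col10a1 (300.5 CPM), all cartilage genes. Vehicle replicate 2 of 48 h stood apart for Trib3 (15.96 CPM) and replicate 5 for Derl3 (1.266 CPM). For whole libraries, 50 µM replicate 3 of 48 h had 24.53 M counts, apart from the rest of its group, and 10 µM replicate 2 of 48 h had 0.4471% muscle transcripts.

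The interaction test called 122 genes for the difference between 24 and 3 h, a count for which chance is not excluded. Of 301 pairs of a named gene and an interaction, 64 were called. Many of these genes were named for small p-values in these tests or for calls at 50 µM, so that share does not describe all genes. Over all 19247 genes, 122, 0 and 375 were called between 24 and 3 h, 48 and 24 h, and 48 and 3 h. For the sterol and lipid genes the difference in log2 fold change between 24 and 3 h was -0.78 for Fdft1, -0.72 for Cyp51, -0.90 for Nsdhl, -0.80 for Dhcr7, -0.92 for Insig1, -1.02 for Idi1, -0.52 for Hmgcs1, -0.56 for Sqle, -0.77 for Msmo1, -0.73 for Scd1, -0.30 for Fads1, -0.52 for Fads2 and -0.88 for Cpt1a. For Dhcr7 and Cyp51, which rose at both times, this is a smaller rise, while Cpt1a was below vehicle at 24 h. For the muscle genes the difference was -1.46 for Casq1, -0.97 for Mylpf, -1.14 for Tnnt3, -0.84 for Tnnc1, -1.97 for Atp1b4, -1.01 for Myh8 and -0.81 for Myl1. Beyond these it was -0.76 for Id1, -1.14 for Acta2 and 0.33 for Srsf3, which had fallen at 3 h.

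Between 48 and 3 h the effect of 50 µM differed for 375 genes. Muscle and associated genes had lower effects at 48 h, by -2.17 for Myh7b, -1.88 for Apobec2, -1.59 for Myh3, -1.64 for Fgf6, -2.22 for Csrp3, -1.24 for Casq1, -1.40 for Mylpf, -1.27 for Tnnt3, -1.22 for Tnnc1, -2.86 for Atp1b4, -1.60 for Myh8, -1.26 for Myl1 and -1.04 for Acta2. The sterol and lipid genes followed, at -0.62 for Dhcr7, -0.55 for Cyp51, -0.79 for Insig1, -0.71 for Idi1, -0.43 for Hmgcs1, -0.57 for Sqle, -0.45 for Msmo1, -0.67 for Scd1, -0.43 for Fads2, -0.65 for Abcg1, -0.73 for Apoe and -0.69 for Cpt1a. For Dhcr7, Cyp51, Hmgcs1, Sqle and Scd1, which rose at both times, this is a smaller rise. For Abcg1, which fell at both, it is a deeper fall, and Apoe and Cpt1a were below vehicle at 48 h. Lower effects at 48 h were also found for AW551984 (-1.21), Glt8d2 (-1.18), Id1 (-0.83), Csf1r (-1.11), Tnmd (-1.09), Fmod (-0.79), Aldh1a3 (-1.10) and Col1a2 (-0.40). Higher effects at 48 h were found for Atf5 (0.83), Cth (1.05), Trib3 (0.95), Gsta4 (0.60), Fgfr3 (0.45) and Bambi (0.47). Tuba1a (0.46) and Srsf3 (0.32), which had fallen at 3 h, had a less negative effect at 48 h.

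Muscle transcripts were lower with 50 µM at 48 h. Epidermal content of the libraries was argued against as the cause, since with the epidermal score as a covariate 24 of the 24 called muscle genes were still called. A lower share of every cell type other than cartilage was argued against as well, since the endothelial list had a median log2 fold change of -0.06 over 17 members, 0.901 above that of the muscle list (SE 0.111). The SEs of medians given here come from resampling genes and leave out the spread between libraries. A lower share of all muscle-lineage cells and a change in maturing muscle alone cannot be told apart, because the early myogenic genes Pax3, Pax7, Myf5 and Myod1, at -0.57, -0.96, -1.56 and -0.08, had a median only 0.222 above that of the other members, with an SE of 0.373. The fall itself came from a list and a comparison with vehicle fixed before the data were examined, though its camera call was lost with an estimated correlation. What lies behind the fall is left as a hypothesis, weighed on the same data.

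The ribosomal RNA mt-Rnr1 was higher with 50 µM at 3, 24 and 48 h, in libraries made from poly(A)-selected RNA. More carry-over of RNA was argued against for nuclear transcripts of types that lack a poly(A) tail. They had median log2 fold changes of -0.13 ± 0.04 (100 transcripts, ± SE), -0.0278 ± 0.0922 (79) and -0.16 ± 0.08 (67) at the 3 times. These SEs, like the next, come from resampling transcripts and leave out the spread between libraries. The transcripts were picked by gene name and type, and reads of overlapping genes cannot be told apart. Carry-over of the mitochondrial ribosomal RNA itself is therefore not excluded. More mitochondrial RNA of every kind was argued against, since the 13 mitochondrial messenger RNAs had a median of -0.395 at 3 h (SE 0.0638), with -0.19 at 24 h and -0.05 at 48 h. A change in the making, tailing or decay of the ribosomal RNA may account for it and was not tested.

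Genes lower with 50 µM at 48 h were often genes that rose in vehicle between 3 and 24 h, 510 of 871 where independent lists would share 148, while genes higher with 50 µM held more than expected both of those that rose (157 against 110) and of those that fell (131 against 90.2). These comparisons have no library in common, so shared controls were argued against by the ratio of 3.45 for the lower genes. Muscle transcripts alone were argued against, since without the 321 genes that followed the muscle score (correlation over 0.5) the count was 315 of 665 against 104, a ratio of 3.02. A delay of all changes of culture time was argued against by the higher genes that rose in vehicle (157 against 110), though genes are not independent. The chondrocyte list, which rose in vehicle, does not decide it, with a median of 0.143 at 48 h and members that went both ways. A slower course of part of the tissue's changes is left open for the lower genes alone.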

How the results depend on the processing

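The epidermal covariate and the refits on fixed genes were the alternatives chosen after seeing the data. Of 212 called results for named genes, 192 were called under every alternative run and 202 under every alternative other than leaving out a library or adding the epidermal covariate, and none of them changed sign while called. Of the list results, 80 were lost and 0 gained with an estimated correlation, 56 lost and 4 gained with fry, and 81 lost and 95 gained over all fits that left out a library. In 1 of these the direction reversed, the glycolysis and hypoxia list with 10 µM at 24 h, at an adjusted p of 0.00418 without 10 µM replicate 4 (from 0.000146 to 0.107 over the libraries left out). The cause was not tested for any change given here, except that fits without a library hold fewer samples. Median-of-ratios factors and the stricter filter moved no count of calls by over 1.5 times. The planned pseudocounts and filters for files with normalized values alone were not run, since the files hold counts.

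DESeq2 called 574, 994 and 16 genes for 50 µM at 3 and 24 h and 10 µM at 3 h (239, 585 and 0 by edgeR), 17 and 53 for 10 µM at 24 and 48 h (0 and 1 by edgeR), 254 for 50 against 10 µM at 24 h (154), and 218 and 4 for the differences of 24 from 3 h and of 48 from 24 h (122 and 0). With all 45 libraries in 1 fit the counts were 468 and 888 for 50 µM at 3 and 24 h, and 12, 4 and 20 for 10 µM at 3, 24 and 48 h. For 50 against 10 µM at 3 h, a fit of those groups alone called 21 (120). Without a filter, 3 and 22 genes were called for 10 µM at 24 and 48 h, with upper-quartile factors 0 at 48 h, and with the epidermal covariate 9 and 15.

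With the replicate block, 1146 genes were called for 50 µM at 24 h, 2583 at 48 h, 97 for 10 µM at 24 h and 38 at 48 h (47 with the numbers of the library codes), and the block moved no other count of calls by over 1.5 times. The filter on low counts keeps more genes with the block or covariate in the design, and refitted on the genes kept without them, a check made after seeing the data, the block gave 1180, 2598, 95 and 37 (58) and the covariate 749, 1783, 9 and 16 for 50 µM at 24 and 48 h and 10 µM at 24 and 48 h. Of results for named genes, 10 gained a call with the block and 0 lost it. Of list results, 3 were lost and 15 gained with the block, and 5 gained and 0 lost with the code numbers. At 50 µM and 24 h the numbers do not pair every library, since the lowest correlation was 0.0356 and 8 of 10 libraries correlated best with their own number. Neither do they for 50 µM at 3 h (lowest 0.0385, 7 of 10), 10 µM at 3 h (-0.0191, 6 of 10), the vehicle times (-0.112, -0.0374 and -0.00115, with 3, 5 and 4 of 10) or 50 against 10 µM at 3 and 24 h (-0.242 and 0.0371, with 4 and 8 of 10), and at 48 h only the code numbers do (lowest 0.149, against 0.0182 with the title numbers).

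Lists that passed numbered 3 and 5 (estimated correlation and fry, 12 by camera) for 50 µM at 3 h, 2 and 3 (9) for 10 µM at 3 h, 0 and 0 (19) at 24 h and 0 and 2 (14) at 48 h, and with an estimated correlation 2 (20) and 1 (14) for 50 µM at 24 and 48 h. At a threshold of 0.01, 26, 38 and 152 genes overlapped in the same direction between 3 and 24 h, 3 and 48 h, and 24 and 48 h (82, 109 and 438 at 0.05).

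Leaving out each library in turn gave 141 to 289 genes for 50 µM at 3 h, 345 to 659 at 24 h and 1111 to 1370 at 48 h, and 0 to 5, 0 to 0 and 0 to 1 for 10 µM. It gave 4353 to 5054, 1049 to 1541 and 7294 to 7648 in vehicle (24 against 3 h, 48 against 24 h, 48 against 3 h), 73 to 138, 65 to 127 and 388 to 576 for 50 against 10 µM, and 82 to 172, 0 to 2 and 290 to 414 for the differences between times. Lists that passed ranged from 10 to 14, 15 to 25 and 13 to 15 for 50 µM and from 9 to 12, 15 to 23 and 12 to 17 for 10 µM. This depth and number of libraries limit what the differences between times can show, since in simulated data 1.5-fold differences were recovered for 34.3% of changed genes between 24 and 3 h, 28.4% between 48 and 24 h and 40.3% between 48 and 3 h.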

Other observations

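The gene families of the next paragraph, the counts by replicate number and the structure of the other splits were chosen only after the results were seen, and so were the splits of 50 µM at 3 h and 48 h and of 10 µM at 24 h and 48 h.

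Alpha- and beta-tubulin genes, which encode the subunits of microtubules, fell together at 3 h with 50 µM, 10 of 12 measured members with a median log2 fold change of -0.58 (9 with upper-quartile factors). At 24 h 6 of 11 fell, with a median of -0.29, and at 48 h 4 of 12 fell and 1 rose. Cells are known to degrade tubulin messenger RNA when unpolymerised tubulin builds up, which was not tested here, and reads shared between near-identical tubulins leave the values of single members uncertain. Of 11 SR splicing factor genes, 3 fell at 3 h, 0 were called at 24 h and 1 fell at 48 h (0 with median-of-ratios factors). Cytosolic aminoacyl-tRNA synthetase genes, which charge transfer RNA with amino acids and are known targets of the integrated stress response, were called in 0 of 20 cases at 3 h, rose in 3 at 24 h and in 9 at 48 h, or 10 with the other factors. The families were picked after members had been seen to move, so the counts describe them and no test of them is given. The median log2 fold change of all genes lay between -0.00571 and 0.00772 under every scaling at every time.

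Other lists moved at 50 µM without a place among those described. At 3 h, 2 of 31 glycolysis and hypoxia genes fell (1 higher and 5 lower adjusted over the list alone), with camera at an adjusted p = 0.00951 and an adjusted p = 0.429 with an estimated correlation, and 3 of 16 Hedgehog genes fell. At 48 h, 4 of 26 p53 targets rose (camera adjusted p = 0.00569, and adjusted p = 0.516 with an estimated correlation), 2 of 20 interferon genes fell (0.0254, and adjusted p = 0.617 with an estimated correlation) and 1 of 30 G2/M genes fell (0.000788, and adjusted p = 0.617 with an estimated correlation).

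The epidermal score followed the replicate number of the library codes across groups. Number took 90.8%, 82.1% and 84.3% of the variance of the score within groups over the 15 libraries of 3, 24 and 48 h, with permutation p-values of 0.00032, 0.00035 and 0.00043 (one-sided, 100000 permutations of the numbers within groups, each 0.00043 when adjusted over the 3 times). The labels do not say what a number marks. With the epidermal score as a covariate, 717 genes were called for 50 µM at 24 h and 1763 at 48 h.

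Limbs of both sexes were cultured together per the labels, and transcripts of the X-linked Xist and the Y-linked Ddx3y were both found in all libraries other than those named next, with 524.5 ± 107.3 and 72.46 ± 10.8 CPM in vehicle at 3 h (mean ± SD, n = 5). Ddx3y had 0 counts in 10 µM replicate 4 of 3 h, which allows up to 0.134 CPM, and 0.144 CPM in 10 µM replicate 5 of 24 h. Xist was at 2.17 CPM in 10 µM replicate 2 of 48 h, where Ddx3y was at 118 CPM. The mix also differed at 3 h with 50 µM, where Ddx3y ranged from 29.42 to 61.7 CPM against 60 to 86.96 in vehicle and Xist from 365.7 to 1211 against 415.7 to 655.5, and the lower Eif2s3y there is not ascribed to bisphenol A. The limit for a count of 0 takes 3 counts of the library's total and covers counting error only.

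In the authors' deposited tables, 499, 920 and 1972 genes had an adjusted p-value under 0.05 for 50 µM at 3, 24 and 48 h, and 13, 15 and 52 for 10 µM. Of the genes called here for 50 µM, 239 of 239, 583 of 585 and 1531 of 1536 were among them, with 0 in the opposite direction.

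Other splits of the libraries tested whether the counts of called genes could arise without regard to the label of interest. For 50 µM the real counts of 239, 585 and 1536 were reached by 2, 1 and 1 of 100 splits with the real split counted, and the highest other counts were 313, 64 and 1. Chance labelling of these libraries can be excluded at 24 and 48 h, though at 48 h these splits ignore the pairing. The labels do not say whether the libraries came from separate litters or culture days. A chance difference between cultures is therefore not excluded, here or for the counts below, where chance means such labelling. At 3 h 2 of 100 is a share under 0.05, which argues against such chance labelling for the count of 239. A mixed split nevertheless called more genes than the real one. The split with 313 genes set vehicle replicates 2 and 3 with 50 µM replicates 2, 4 and 5, and its fold changes followed gene length (Spearman's rho of -0.338 across 16988 genes, which are not independent, against -0.0946 in the real split), which points to a structure of these libraries. The real split of 10 µM at 3 h followed length almost as much (-0.329), so its list results are not free of such a structure. For 10 µM at 48 h, the count of 1 was reached by 9 of 100 splits, with a highest other of 128, so chance cannot be excluded. At 3 and 24 h the counts were 0, which all 100 splits reach whatever they call (highest others 1 and 559), so these splits say nothing about chance. The split with 559 genes had the largest epidermal difference of the 100 (2.26 in the score), and in the split with 128 it was 1.85, a structure of the libraries other than dose. Where numbers pair a dose with vehicle, the real split was also set against the others among 16 that part every pair. The counts were 1536 against a highest other of 0 for 50 µM at 48 h, 1 against 0 for 10 µM at 48 h and 0 against 0 for 10 µM at 24 h, with too few such splits for a share under 0.05. This was not run for 50 against 10 µM at 48 h, which the code numbers pair. For the vehicle times, 5131, 1432 and 7901 were reached by 1 of 100 splits each, against highest others of 1, 137 and 2, and chance can be excluded. The split with 137 had the largest epidermal difference of its 100 (2.13). For 50 against 10 µM, 120, 154 and 605 were reached by 1 of 50 splits each, against 17, 8 and 227, and chance can be excluded, though at 48 h these splits ignore the pairing. The difference of 48 from 3 h (375) was reached by 2 of 50, highest other 924, and that of 24 from 3 h (122) by 4 of 50, highest other 1307. These splits mix the doses within each time and so do not keep an equal dose effect at both times. They therefore cannot decide whether chance gives such counts of differences. For the difference of 48 from 24 h the count of 0 is reached by all 50 whatever they call (highest other 549), so nothing follows. Behind the counts of 0, which are from edgeR, stood 974, 786 and 645 genes at an unadjusted p under 0.05 (850, 853 and 962 expected by chance) for 10 µM at 3 and 24 h and the difference of 48 from 24 h, where DESeq2 called 16, 17 and 4. The split with 924 exchanged all labels of 48 h and so held the dose effect itself, and the split with 1307 mixed the libraries of 24 h, with an epidermal difference of 1.17 that 6 of 50 splits reached.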
